A study of Homo sapiens with 7 samples.

How the data were processed

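Total RNA of 7 xenograft tumors was labelled from 150 ng each and read on 1 Affymetrix human array per tumor, per the labels' protocols. The values were made with Affymetrix Expression Console version 1.1 and RMA (robust multi-array averaging, which corrects background, quantile normalizes and summarises probes on the log2 scale), per the submitters' processing notes. The settings used are not given in the sources used here. RMA values carry no detection call, so whether a low value is signal is unknown, and the background control probe sets, which read 3.43 to 4.57, were used as a guide. The number of arrays limits the precision.

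The deposited log2 values had lost their decimal point in all but 58 of 345702 cells. The point was put back after the first digit, or after the second where the first digit was 1. The recovered values ran from 2.98 to 14.3. This was checked in 3 ways. No value starting with 1 had a second digit over 4. The 58 values that kept a point lay a median of 0.137 (at most 0.608) from the recovered values of the same probe set in the same group. Correlations between JeKo-1 tumors were 0.532 to 0.577 as deposited and 0.987 to 0.993 after recovery. The plan assumed log2 values, and its tests were kept. No 2 arrays were identical and no column was left unused.

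Of the probe sets, 93 are controls, 45259 have 1 gene symbol in the platform annotation, 1327 have several and 2713 others have none. Only probe sets with 1 symbol were named. Entrez IDs of 45178 matched the RefSeq gene table of the GRCh38.p14 assembly, and 0 symbols changed. That table was used for names and gene order only. A gene was represented by its probe set with the highest mean over all tumors; 11822 of the 18239 genes had more than 1. Among 1084 genes with at least 2 probe sets past the test and changed at least 2-fold, 7 had probe sets in opposite directions.

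The groups are those of the labels. JBR tumors were compared with JeKo-1 tumors by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were fixed before the data were examined. Of their 519 genes 487 were measured; some genes are not reported here. The 30 lists were tested with camera at a preset correlation of 0.01, adjusted over all lists. Camera compares a list with the other genes, on moderated statistics. Mean, median and test differ in sign for the endothelial, erythroid, immunoproteasome and oxidative phosphorylation lists, none of which passed. Array controls were compared by exact permutation over the 21 splits of the tumors.

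Named genes followed a rule fixed beforehand. It took the 12 largest positive and 12 largest negative differences among genes past the threshold whose groups did not overlap, leaving out systematic names such as LOC or orf symbols. It added 12 fixed genes, and up to 2 members per list and direction, or the member with the smallest p where none passed. Not all genes of the last part are printed. One sex-linked transcript among the 12 largest falls is left out.

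The fit was tested on simulated data for 18239 genes with the real means and 200 changed genes. Residual spreads were the real ones, assigned to genes at random. The fit recovered 16% of genes changed by 0.5, 76% by 1, 98% by 2 and 100% by 4 log2 units. It called 3 of 18039 unchanged genes. Far fewer genes changed than in the data, where 5455 passed, so these shares need not hold for the real comparison. Camera called the 1 list shifted in simulation and 0 others. Genes were drawn independently there, so the simulation does not show how camera behaves when genes are correlated.

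Alternatives covered the normalization, filters on dim genes, the choice of probe set, the variance model, array weights, tumor number as a block, each tumor left out, and other list tests. Tests of explanations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.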

Results

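Gene expression was measured on 1 array per tumor in 7 human mantle cell lymphoma xenografts grown under the skin of CB-17 SCID mice and harvested 27 days after inoculation, without treatment. Of these, 5 tumors grew from JeKo-1, an established mantle cell lymphoma line that is sensitive to the proteasome inhibitor bortezomib, and 2 from JBR, a bortezomib-resistant mantle cell lymphoma line. The comparison asks how untreated tumors of the resistant line differ in expression from tumors of the sensitive line. The arrays carried 49386 probe sets, of which 18239 genes were represented by a probe set of their own. Array medians lay between 4.61 and 4.65 on the log2 scale. Pairs of JeKo-1 tumors correlated at Pearson r = 0.987 to 0.993 across probe sets, the pair of JBR tumors at 0.991, and pairs from different groups at 0.936 to 0.947. The labels number the tumors but do not say that each came from its own mouse, so the p-values measure the spread between these tumors. With 2 JBR tumors, 21 splits of the tumors exist and an exact two-sided permutation p cannot fall under 0.0476.

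JBR tumors carried high levels of the plasma cell genes SDC1 and PRDM1, which averaged under 5 in JeKo-1 tumors, and lacked the signal of many genes that were abundant in JeKo-1 tumors. Expression differed for 5455 of the 18239 genes, 2589 of them higher and 2866 lower in JBR tumors (limma, adjusted p under 0.05). Of these, 898 were at least 2-fold higher and 1268 at least 2-fold lower. The probe set of each gene was the brightest over all 7 tumors, 5 of them JeKo-1, which can favour falls in JBR tumors. With all probe sets of a gene averaged, 2685 genes were higher and 2687 lower, so the excess of falls was not kept. In 5409 of the 5455 genes the values of the 2 groups did not overlap; over all genes the groups did not overlap in 41.4%, where chance gives 9.5%. Background control probe sets read between 3.43 and 4.57, so differences from or to such levels are understated. With only the 8185 genes of at least 6 on average tested, 4473 differed. Counts within lists of expressed genes are to be read against that share.

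Among the genes with the largest rises in JBR tumors, the immunoglobulin lambda locus, IGL, read 13.21 ± 0.04 (SD, n = 2) against 5.38 ± 2.05 (SD, n = 5). SDC1, the plasma cell surface proteoglycan syndecan-1, read 11.41 ± 0.16 against 4.71 ± 0.50, a difference of 6.70 ± 0.29 (SE; adjusted p = 1.63e-07). UNC13C, a synaptic vesicle priming factor, rose by 7.18, NPTX1, a neuronal pentraxin, by 6.61 and CAV1, the caveolar coat protein caveolin-1, by 6.31. CLEC7A, the beta-glucan receptor dectin-1, rose by 5.94, HBEGF, a ligand of the EGF receptor, by 5.78 and LMO3, a LIM-only transcriptional cofactor, by 5.74. IGLL1, a surrogate light chain gene whose sequence resembles the lambda constant genes, rose by 5.68, and BEST3, a chloride channel gene, by 5.61. BAHCC1 rose by 5.39 and TNFRSF19, a receptor of the TNF family, by 5.22. The JeKo-1 tumors were not uniform for these genes. IGL read 9.03 in JeKo-1 tumor 1 and 4.25 to 4.69 in the other 4, and UNC13C, NPTX1, CAV1 and IGLL1 were also highest in that tumor. Without JeKo-1 tumor 1, 5735 genes differed.

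The largest fall in JBR tumors was that of PCDH9, a protocadherin, from 12.12 ± 0.70 (SD, n = 5) to 4.09 ± 0.74 (SD, n = 2), although another probe set of PCDH9 was higher in JBR tumors by 2.87. TCL1A, a coactivator of AKT kinase in B cells, differed by -7.44 ± 0.28 (SE; adjusted p = 6.33e-08) and CDKN2A, which encodes the cell cycle inhibitors p16 and ARF, by -7.31 ± 0.17 (adjusted p = 5.83e-09). The next were MAGEB2, a cancer-testis antigen, at -6.95, YBX3, a cold shock domain protein, at -6.87, and SMAD1, a transducer of BMP signals, at -6.87. NOL4 differed by -6.71 and GTSF1, a germline factor of the piRNA pathway, by -6.61. GNB4, a G protein beta subunit, differed by -6.38, BMP7, a bone morphogenetic protein, by -6.32, and IFI27, an interferon-induced gene, by -6.28. JeKo-1 tumor 1 was the lowest JeKo-1 tumor for SMAD1, at 9.63, and for GNB4, at 9.50.

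**Figure D1:**
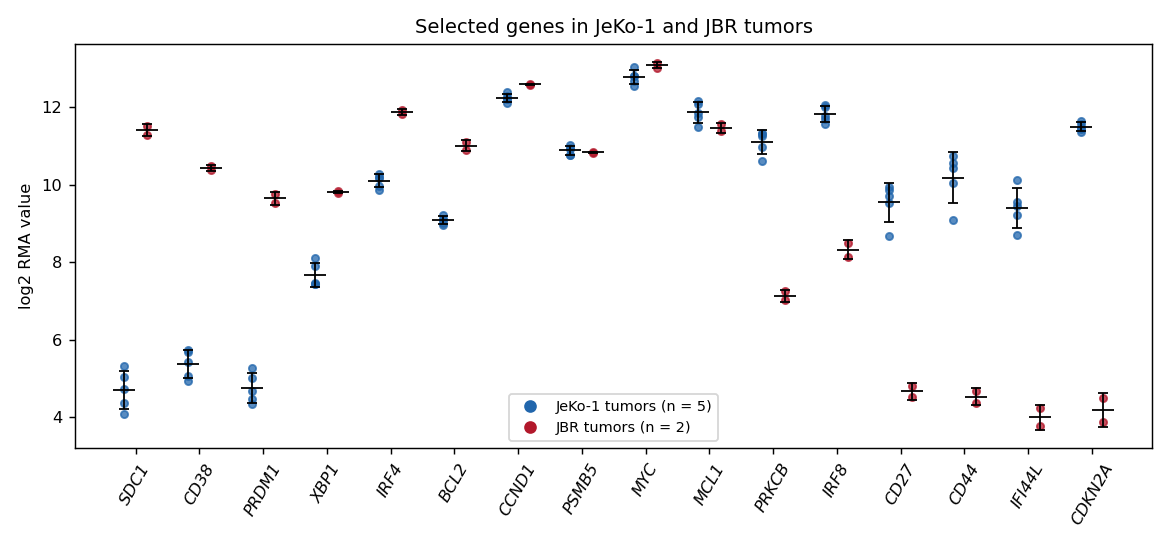
Log2 RMA values (vertical axis) of selected genes (horizontal axis) in each JeKo-1 tumor (blue, n = 5) and JBR tumor (red, n = 2); black marks are means with SD. SDC1, CD38 and PRDM1 lie higher, and CD27, CD44, IFI44L and CDKN2A lower, in both JBR tumors than in all JeKo-1 tumors, while values of PSMB5 differ by -0.05.

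Genes of plasma cell differentiation were higher in JBR tumors. Of the 24 measured, 13 rose, 3 fell and 8 did not pass the test (16 passed when adjusted over the list alone), and the mean difference was 1.45. Besides SDC1, the ectoenzyme gene CD38 rose by 5.07 ± 0.22 (SE; adjusted p = 1.68e-07). PRDM1, the repressor BLIMP-1 that ends the B-cell programme, rose by 4.90 ± 0.24. XBP1, a transcription factor of secretory cells, rose by 2.15 and IRF4, which is needed for plasma cell formation, by 1.78. The B-cell coactivator POU2AF1 differed by -0.80, and CD27, a memory B-cell and plasma cell receptor, fell from 9.55 ± 0.52 to 4.67 ± 0.21. The list stood apart from other genes (camera, adjusted p = 2.21e-05), and its call held with an estimated correlation (adjusted p = 0.0499).

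Genes of B-cell identity were lower in JBR tumors. Of the 24 measured, 17 fell, 2 rose and 5 did not pass the test (21 passed when adjusted over the list alone), with a mean difference of -1.51 (camera, adjusted p = 2.35e-07; adjusted p = 0.0454 with an estimated correlation). After TCL1A, the largest fall was that of IRF8, a transcription factor of germinal centre B cells, from 11.83 ± 0.21 to 8.33 ± 0.26. EBF1, an early B-cell transcription factor, rose by 1.13 and CIITA, the class II transactivator, by 1.08.

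Genes of B-cell receptor signalling went both ways, with 9 of 17 lower, 4 higher and 4 not past the test (14 when adjusted over the list alone). PRKCB, the kinase that links the receptor to NF-kB, differed by -3.97 ± 0.20 (SE; adjusted p = 4.29e-07), and the adaptor BLNK by -1.95. EGR1, an early response gene, rose by 2.90 and MALT1, a paracaspase of the same route, by 1.16. The list missed the threshold (camera, adjusted p = 0.0902), and without JBR tumor 1 it passed (adjusted p = 0.0422). Of 20 NF-kB targets, 5 rose and 3 fell (9 passed when adjusted over the list alone; camera, adjusted p = 0.527). The chemokine gene CCL3 rose by 3.42, but unevenly, to 8.99 in JBR tumor 1 and 6.24 in JBR tumor 2. TNFAIP3, an inhibitor of NF-kB, rose by 3.24, while REL, an NF-kB subunit, differed by -1.91.

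Interferon response genes were lower in JBR tumors. Of the 25 measured, 23 fell, 1 rose and 1 did not pass the test (24 passed when adjusted over the list alone), with a mean difference of -2.91. After IFI27, IFI44L fell from 9.41 ± 0.52 (SD, n = 5) to 4.00 ± 0.33 (SD, n = 2), and IRF1, a transcription factor of the interferon gamma response, rose by 0.88. The list had the lowest p of the 30 tested (camera, adjusted p = 4.21e-18), and its call was lost with an estimated correlation (adjusted p = 0.146).

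Unfolded protein response genes were higher in JBR tumors, with 13 of 23 higher, none lower and 10 not past the test (13 passed when adjusted over the list alone), a mean difference of 0.73. The pseudokinase gene TRIB3 rose by 1.71 and ATF3, a stress transcription factor, by 1.70. The list passed with camera (adjusted p = 5.91e-05) and was lost with an estimated correlation (adjusted p = 0.146). Of 17 oxidative stress genes, 10 rose and 2 fell (13 passed when adjusted over the list alone; camera, adjusted p = 0.0155, and adjusted p = 0.146 with an estimated correlation). With only genes of at least 6 on average the oxidative stress list missed the threshold (adjusted p = 0.0647). SLC7A11, the cystine importer, rose by 1.94. GPX1, a glutathione peroxidase, differed by -3.88 and GCLC, which starts glutathione synthesis, by -1.55. Of 19 heat shock genes, 3 rose and 3 fell (6 passed when adjusted over the list alone; camera, adjusted p = 0.482), and the autophagy receptor gene SQSTM1 rose by 0.86, a call lost with a probe set without the _x_at or _s_at ending (0.50) that read only 4.58 and 5.08.

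Among proteasome genes, PSMB5, the catalytic subunit that bortezomib binds, read 10.84 ± 0.01 (SD, n = 2) against 10.89 ± 0.12 (SD, n = 5), a difference of -0.05 ± 0.12 (SE; adjusted p = 0.811). Of the 15 genes of the 20S core, 5 rose and 10 did not pass the test (8 passed when adjusted over the list alone, 1 of them lower), led by PSMA3 at 0.88 (camera, adjusted p = 0.115). Averaging all probe sets of a gene brought the core past the threshold (adjusted p = 0.0355). Of 16 measured genes of the 19S particle, 4 rose and 1 fell (5 passed when adjusted over the list alone; camera, adjusted p = 0.531), where PSMD14, a deubiquitinase subunit, rose by 0.98 (adjusted p = 0.0035, and 0.0522 without JBR tumor 2), PSMC4 rose by 0.57 and PSMD5 differed by -1.10. None of the 4 immunoproteasome genes passed the limma test (1 had an unadjusted p under 0.05, none passed when adjusted over the list alone; camera, adjusted p = 0.98), and PSME1, with the smallest p, differed by 0.29; it passed without JeKo-1 tumor 1, at 0.34, with all probe sets averaged, also at 0.34, and with an intensity trend in the variance.

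Regulators of cell death changed in both directions. BCL2, the anti-apoptotic founder of its family, rose from 9.09 ± 0.10 (SD, n = 5) to 11.01 ± 0.14 (SD, n = 2), while the kinase gene PIM1 differed by -2.32. MCL1, another anti-apoptotic gene, differed by -0.40 ± 0.18 (SE; adjusted p = 0.126), and by -0.50 without JeKo-1 tumor 1, where it passed the test. Of 10 anti-apoptotic genes, 2 rose and 4 fell (7 passed when adjusted over the list alone; camera, adjusted p = 0.512). Of 17 pro-apoptotic genes, 8 rose and 3 fell (11 passed when adjusted over the list alone; camera, adjusted p = 0.127). BIK, a BH3-only gene, rose by 4.10 and the death receptor gene FAS by 3.52, while the initiator caspase CASP8 differed by -1.10 and CASP9 by -0.79.

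Growth genes differed little as groups. MKI67, a marker of dividing cells, differed by 0.37 ± 0.24 (SE; adjusted p = 0.304), and MYC by 0.31 ± 0.14 (adjusted p = 0.144, and adjusted p = 0.044 with an intensity trend in the variance). Averaging the probe sets brought MKI67 past the threshold, at 0.75. Of 26 proliferation genes, 9 rose and 3 fell (12 passed when adjusted over the list alone; camera, adjusted p = 0.27), and BUB1, a spindle checkpoint kinase, rose by 2.21. Of 23 MYC and ribosome biogenesis genes, 3 rose and 3 fell (5 passed when adjusted over the list alone; camera, adjusted p = 0.512), with FBL, a nucleolar methyltransferase, 0.79 higher. Of 16 translation genes, 5 rose and 1 fell (6 passed when adjusted over the list alone; camera, adjusted p = 0.153), led by the initiation factor EIF4B at 1.32; the list passed with all probe sets averaged (adjusted p = 0.0324). Of 18 oxidative phosphorylation genes, 4 rose and 1 fell (2 passed when adjusted over the list alone; camera, adjusted p = 0.98). ATP5F1A, an ATP synthase subunit, differed by -0.83.

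Hallmark genes of mantle cell lymphoma went both ways, with 6 of the 13 measured lower and 4 higher in JBR tumors (11 passed when adjusted over the list alone; camera, adjusted p = 0.27). CCND1, the cyclin D1 gene that the disease's translocation activates, read 12.59 ± 0.01 (SD, n = 2) against 12.24 ± 0.10 (SD, n = 5), and its adjusted p of 0.0417 rose above the threshold without any 1 of JeKo-1 tumors 1 to 4 or of the JBR tumors (0.0595 without JeKo-1 tumor 1), with the array median subtracted (0.0592) and with repeated quantile normalization (0.0971). SOX11, a transcription factor typical of the disease, rose by 1.13, a call lost without JBR tumor 1 (0.83, adjusted p = 0.22) and with a probe set without the _x_at or _s_at ending (0.56). NOTCH1 rose by 2.14, and ATM, the DNA damage kinase, differed by -2.41.

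**Figure D2:**
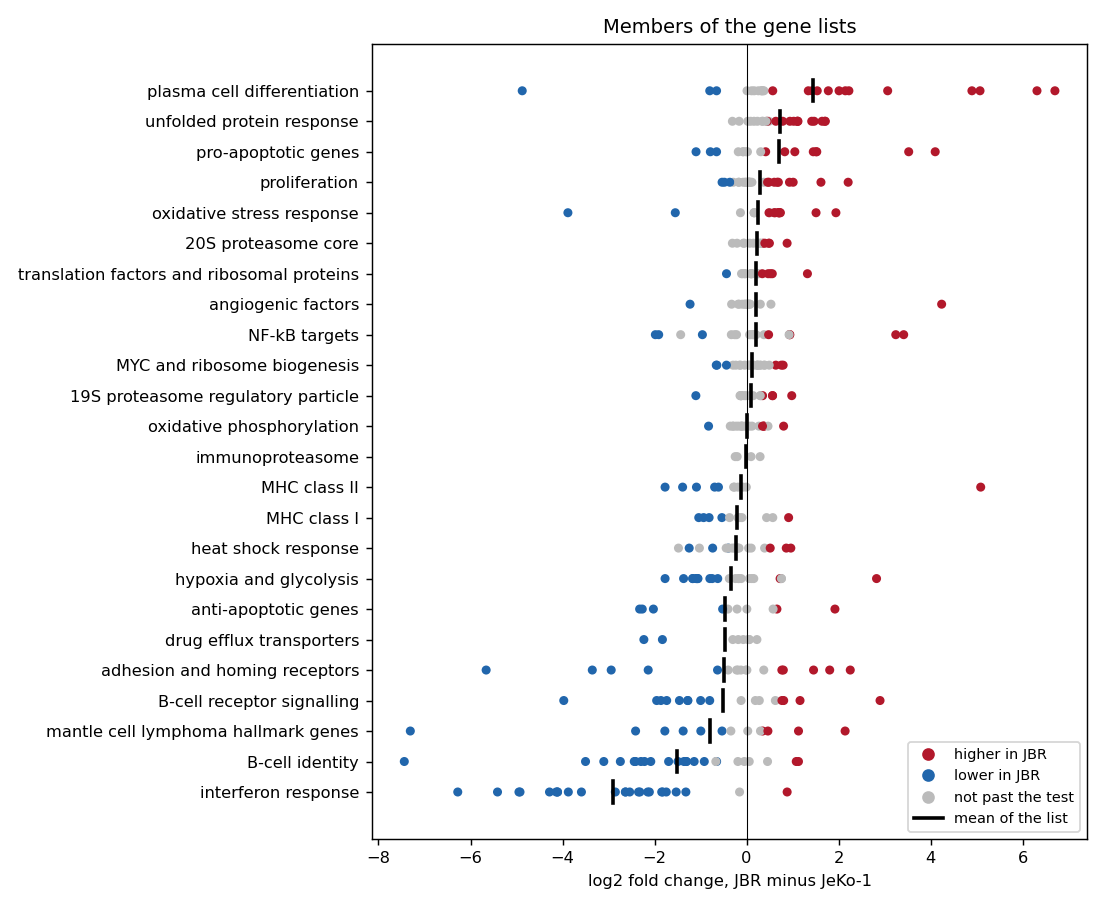
Log2 fold change of JBR against JeKo-1 tumors (horizontal axis) for each measured member of the gene lists (vertical axis); red and blue points passed the limma test, grey points did not, and black bars are list means. Interferon response genes have the lowest mean, -2.91, and plasma cell genes the highest, 1.45.

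Some antigen presentation genes gave readings that depended on the probe set. HLA-DQB1, a class II chain, rose from 4.94 ± 0.34 (SD, n = 5) to 10.03 ± 0.01 (SD, n = 2), while its 2 probe sets without the _x_at or _s_at ending read 3.71 to 4.37, within the range of the background controls. HLA-DQA1 differed by -1.39 with its brightest probe set and by 2.26 with all its probe sets averaged, and HLA-C, a class I heavy chain, by -1.04 and 1.30. HLA-DOB, a modulator of class II loading, differed by -1.77. Of 11 class II genes, 5 fell and 1 rose (6 passed when adjusted over the list alone; camera, adjusted p = 0.0411), and the call was lost with an estimated correlation (adjusted p = 0.542). It was also lost without JeKo-1 tumor 1, 2 or 3 (adjusted p = 0.0859, 0.054 and 0.0646) and without JBR tumor 1 (adjusted p = 0.0808), with all probe sets averaged (adjusted p = 0.965) and with either filter on dim genes (adjusted p = 0.192 and 0.221). Of 11 class I genes, 4 fell and 1 rose (7 passed when adjusted over the list alone; camera, adjusted p = 0.334).

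Of 23 genes of hypoxia and glycolysis, 11 fell and 2 rose in JBR tumors (13 passed when adjusted over the list alone; camera, adjusted p = 0.0128, and adjusted p = 0.542 with an estimated correlation). That call was also lost with only genes above the median probe set (adjusted p = 0.14) or of at least 6 (adjusted p = 0.278), and without _x_at and _s_at probe sets (adjusted p = 0.105). The glycolytic kinase gene HK1 fell from 9.97 ± 0.17 to 8.20 ± 0.02, and PFKFB4, a regulator of glycolysis, differed by -1.37. The 2 genes that rose were ADM, the vasodilator peptide adrenomedullin, by 2.82 (adjusted p = 0.00989), a call lost without JBR tumor 1 or 2 (adjusted p = 0.0588 and 0.0902), and PDK1, pyruvate dehydrogenase kinase 1, by 0.73 (adjusted p = 0.0335). The call of PDK1 was lost without JeKo-1 tumor 2 or 5 (adjusted p = 0.059 and 0.0594) and with all probe sets averaged (adjusted p = 0.0641). Without JBR tumor 2 the rise of PDK1 shrank to 0.36. Of 16 angiogenic factors, PDGFA, a platelet-derived growth factor, rose by 4.24 and 1 fell (1 passed when adjusted over the list alone; camera, adjusted p = 0.98). Of 17 adhesion and homing genes, 5 rose and 5 fell (11 passed when adjusted over the list alone; camera, adjusted p = 0.527). CD44, the hyaluronan receptor, fell from 10.18 ± 0.66 to 4.52 ± 0.22, and GPR183, an oxysterol receptor that positions B cells, differed by -3.35. The adhesion ligand CD58 rose by 2.25 and the chemokine receptor CCR7 by 1.81. Of 9 drug efflux genes, none rose past the test. ABCB4, a phospholipid exporter, differed by -2.23 and ABCC5, an exporter of nucleotides, by -1.83, the latter a call lost with a probe set without the _x_at or _s_at ending (-0.68) (2 passed when adjusted over the list alone; camera, adjusted p = 0.27).

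Markers of other cell types were mostly near background in both groups. Stroma markers averaged 4.49 in JBR and 4.32 in JeKo-1 tumors, with 1 of 16 past the test (1 when adjusted over the list alone; camera, adjusted p = 0.59). That gene was ACTA2, smooth muscle actin, 2.74 higher in JBR tumors with its _s_at probe set; its 2 other probe sets read 3.74 to 3.87, within the range of the background controls. Of 12 endothelial markers only PECAM1, which B cells also express, passed, at -3.56 (1 when adjusted over the list alone; camera, adjusted p = 0.98). Of 13 myeloid markers 3 fell (3 when adjusted over the list alone; camera, adjusted p = 0.512), among them TYROBP at -2.41 and AIF1 at -2.98, the latter not past the test with a probe set without the _x_at or _s_at ending (-0.28) that read only 4.80 and 4.52. Of 13 T and NK cell markers 3 rose and 1 fell (4 when adjusted over the list alone; camera, adjusted p = 0.482), with the perforin gene PRF1 2.80 higher. None of 5 erythroid and 14 muscle, fat and skin markers passed the limma test (0 and 1 had an unadjusted p under 0.05, none passed when adjusted over the list alone; camera, adjusted p = 0.875 and 0.527). Mouse cells of the host read on this human array only as far as their transcripts bind its probes.

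The RNA quality measure did not differ past its test, which with so few tumors does not show equal quality. The 3′ minus 5′ difference of the GAPDH and ACTB controls averaged 1.07 ± 0.08 (SD, n = 2) in JBR and 1.24 ± 0.15 (SD, n = 5) in JeKo-1 tumors, by -0.17 (exact two-sided permutation p = 0.143). GAPDH alone differed by -0.17 (exact two-sided permutation p = 0.0952) and ACTB alone by -0.17 (exact two-sided permutation p = 0.381). The poly-A spike controls averaged 6.75 ± 0.12 in JBR and 7.18 ± 0.18 in JeKo-1 tumors (exact two-sided permutation p = 0.0476, the smallest this design can give). Array medians averaged 4.65 in JBR and 4.62 in JeKo-1 tumors (exact two-sided permutation p = 0.0476).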

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

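All tests of explanations in this part were chosen after the result was seen. Among 151 results examined for a tumor far from the other JeKo-1 tumors, 17 had one, where chance gives about 1 in 20, or 7.5. Of these, 13 lay in JeKo-1 tumor 1, and in 12 of the 13 that tumor deviated towards the JBR level. That direction was partly set by the choice of genes. IGL, UNC13C, NPTX1, CAV1 and HLA-DQB1 read 3.50 to 4.87 in the other JeKo-1 tumors, where an outlier can hardly lie lower.

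The value of JeKo-1 tumor 1 stood above those of the other 4 for IGL (9.03), UNC13C (6.51), NPTX1 (5.87), CAV1 (6.0), IGLL1 (7.80), PSMA6 (11.92), PSME1 (11.85), TRIB3 (9.12), BIK (6.43), HLA-DQB1 (5.54) and NLRC5 (8.76), and below them for SMAD1 (9.63) and GNB4 (9.50). NLRC5 was the 1 gene that moved away from the JBR level. PECAM1 was highest in JeKo-1 tumor 5 (10.09), CD3G in JeKo-1 tumor 3 (5.78) and SQSTM1 in JeKo-1 tumor 4 (9.81). The poly-A spike controls averaged 7.50 in JeKo-1 tumor 5, against 7.06 to 7.16 in the other JeKo-1 tumors.

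The pattern in JeKo-1 tumor 1 was examined over the 16 genes that read under 5 on average in JeKo-1 tumors 2 to 5 and at least 9 in JBR tumors. All 16 were raised in JeKo-1 tumor 1, by a median of 0.86 log2 units. Raised means above the mean of JeKo-1 tumors 2 to 5, and LMO3 was so by only 0.13. Among the 16, the 11 genes not flagged in that tumor rose by a median of 0.69. The cut at 9 left out TNFRSF19, at 8.96 in JBR tumors, which was not raised. It read 3.74 in JeKo-1 tumor 1 and 3.48 to 3.96 in the other JeKo-1 tumors. For each other JeKo-1 tumor, set against tumors 2 to 5 without itself, 9 to 11 of 16 to 18 such genes were raised, and the median difference was 0.00 to 0.06. The 8291 genes near background in both groups had a median rise of 0.009 in that tumor, so the 16 rose relative to other dim genes. Quantile normalization evens out the level of each array, so this median cannot argue against a higher raw background. A shift of plasma cell genes alone is argued against by the 9 genes that are outside that list and not flagged in that tumor, since all 9 were raised. A small share of JBR material in that tumor may account for these 16 raised genes and cannot be told apart from a change in the tumor itself: the implied shares had a median of 1.84% but ran from 0.18% to 5.31%, a 29.5-fold range, and values near background are not linear. Such a share does not account for SMAD1 and GNB4, which would need 74.0% and 41.2% JBR material, nor for TRIB3, PSMA6 and PSME1, raised in the same tumor, which would need 36.3%, 38.6% and 70.3%. IGLL1 and BIK would need 4.94% and 4.86%.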

How the results depend on the processing

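The alternatives reported here were planned before the data were examined. The count of 5455 genes stayed within 1.5 times under both normalizations, both filters, averaged probe sets, array weights, the trend fit and no moderation (4226 to 5541). Testing every probe set gave 12391 probe sets, 6212 higher, 6179 lower and 4890 at least 2-fold, since more features were tested. Testing against 0.5 log2 units gave 2039 genes, 873 higher and 1166 lower, since small changes no longer count. Leaving out each tumor gave 3922 to 5735 genes (1879 to 2713 higher, 2043 to 3022 lower, 2118 to 2267 at least 2-fold), fewest without JBR tumor 2, and no gene of the 5455 changed sign; without a JBR tumor, the lone one was assumed to vary like the JeKo-1 tumors.

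Tumor number as a fixed replicate block gave 3426 genes, 1507 of them higher, and 4 lists; only numbers 1 and 2 occur in both groups, so tumors 3 to 5 drop out, and the fit to tumors 1 and 2 alone gave the same 3426 and 1507. A random block gave 5457. The difference between tumors 1 and 2 correlated at 0.004 between the groups, so the tumors share only a number.

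Of the 7 lists past the threshold, 2 passed with an estimated correlation and 4 with only genes of at least 6. Fry, which does not compare a list with other genes, gave 17, as did the exact permutation without adjustment. Leaving out a tumor gave 6 or 7. The 3′ to 5′ difference ran from -0.22 to -0.11 without a tumor. Averaged probe sets turned HLA-DQA1 to 2.26 and HLA-C to 1.30, since the probe sets of each moved in opposite directions. Without _x_at and _s_at probe sets ACTA2 gave -0.036 and SDHA -0.067, from probe sets that read 3.69 to 3.87, within the range of the background controls, so these 2 carry no signal to set against the rises. Of 2399 values of named genes under alternatives, 2226 kept direction and side of the threshold, 162 lost the call, 7 gained it and 4 reversed. Signal over background limits the values under about 5.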

Other observations

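In this part, the test over adjacent genes and the splits of the tumors were set before their results were seen, and the tests of genes 50 places apart, of windows and whole chromosomes, of the ATM region and of HLA probe sets were chosen after the result was seen.

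The genes in this paragraph were chosen after their values were seen. PRAME, a cancer-testis antigen, read 10.51 ± 0.15 (SD, n = 5) in JeKo-1 and 4.54 ± 0.17 (SD, n = 2) in JBR tumors. CTCFL, the testis paralog of the insulator protein CTCF, read 11.14 ± 0.27 and 5.10 ± 0.25, and CTAG2, another cancer-testis antigen, 9.83 ± 0.23 and 4.65 ± 0.68. WNT5A, which encodes a secreted signal, read 8.77 in JeKo-1 and 4.37 in JBR tumors, and WNT5B 4.61 and 9.22. In all, 67 genes read at least 8 in every JeKo-1 tumor and under 5 in both JBR tumors, and 17 genes the reverse. JeKo-1 tumor 1 lowers the second count. IGL, UNC13C, NPTX1 and CAV1 read under 5 in JeKo-1 tumors 2 to 5 but 5.87 to 9.03 in tumor 1, so they are left out. The counts of 67 and 17 are thus not to be set against each other. Among the 67 were CYBB, the phagocyte oxidase subunit, ALOX5, the leukotriene-forming lipoxygenase, and CCR2, a chemokine receptor. Among the 17 were ROBO1, a guidance receptor, BAMBI, a decoy receptor for TGF-beta, and MDK, the growth factor midkine.

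The count of 5455 genes was set against all 21 splits of the 7 tumors into 5 and 2. Only 1 split, the real one, gave so many. The highest of the others gave 0 genes with limma (at most 868 at an unadjusted p under 0.05, against 6935). The real split thus ranked first at a share of 0.0476, the smallest that 21 splits can give. In the other splits the difference between the lines adds to the spread within groups, which lowers their counts. The comparison therefore cannot exclude chance as the source of the count.

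Differences ran along chromosomes. Over 7928 autosomal genes with a mean of at least 6, differences of adjacent genes correlated at 0.211, across genes, above the highest of 1000 shuffles of gene order (0.034). Co-regulation of adjacent genes only is argued against by genes 50 places apart, which still correlated at 0.062 (highest shuffle 0.037). Around ATM on chromosome 11, all 21 genes from 10 places before to 10 after were lower in JBR tumors and past the test, by a median of -1.61, and the lowest window of 25 genes, around FAM76B on the same chromosome, had a median of -1.92 (lowest of the shuffles -1.22). The highest window, around RANBP6 on chromosome 9, had a median of 1.68 (highest of the shuffles 0.872). Of the 22 autosomes, 18 had a median past the test against the shuffles, 9 above and 9 below that of all genes (permutation, adjusted p under 0.05). The shuffles treat genes as independent, so the correlation of neighbours can raise this count. Chromosome 9, which holds the highest window, had a median of -0.373. Differences in chromosome copy number between the tumors are a candidate explanation; DNA was not used here.

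HLA and immunoglobulin probe sets rose from a JeKo-1 mean under 5 to a JBR mean of at least 8 in 7 cases. These lay on HLA-C, HLA-DPB1, HLA-DQA1, HLA-DQB1 and IGLL1. None of the 118 probe sets whose symbols start with HLA-, IGH, IGK or IGL went the other way to the same extent. The brightest probe set of IGL rose to 13.21 but is not counted, since its JeKo-1 mean was 5.38. It read 9.03 in JeKo-1 tumor 1 and 4.25 to 4.69 in the other JeKo-1 tumors. JBR is known in the field as a line derived from JeKo-1, which the labels do not state; loss of alleles alone in a derived line is argued against by the 7 rises. In HLA-C and HLA-DQA1, another probe set past the test fell at least 2-fold. The falling probe sets also have the _x_at ending and can bind several transcripts, so they cannot decide whether the probed gene alone changed. A change in the expression of the probed gene alone is argued against in HLA-DPB1, where the 2 probe sets above background without the _x_at or _s_at ending rose by at most 0.305. For HLA-DQB1 and IGLL1 such a change cannot be told apart from other explanations, since 0 of these 2 genes have a probe set of that kind above background. Signal from related genes may account for all 7 rises, as all 7 probe sets are of the kind that can bind several transcripts, but only 1 of the 5 genes has another kind of probe set above background to set against them. Different HLA and immunoglobulin sequences in the groups also stay open, as untested.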
